A study of Rattus norvegicus with 8 samples.

How the data were processed

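RNA of whole rat hippocampi was labelled with Cy3 and hybridised to custom single-colour arrays, per the labels' protocols, with 4 samples of control rats and 4 of rats given fluoxetine after birth (PNFLX). The group and the replicate number of each sample came from its source name. The protocol gives postnatal day 21 as the end of treatment; the sample descriptions give end days that run up to 28 in step with the sample order, and the protocol was followed. The array intensity values (processed signal, mean brightness and local background of each spot) were made with Agilent Feature Extraction, per the file headers, which also state spatial and multiplicative detrending within the array and surrogate values for low signals. They were not normalized between arrays. The flags for spots well above background, saturated or outlying are those of the deposited files. The authors also deposited a table of log2 values. Set against the scanner values, each column matched log2 of the processed signal minus the array's 75th percentile, centred on each probe's median over the 8 arrays, within 0.00241, so its scale and centring are known from the values. Its column medians were 0.06, -0.05, 0.04 and 0.04 for controls 1 to 4 and -0.04, -0.07, 0.10 and -0.13 for PNFLX 1 to 4.

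The values used were log2 of the processed signal minus each array's 75th percentile over the 15207 probes that are not controls, 1 spot each. Over the 8 arrays 521 spots with an outlier flag were left out. Probes well above background on at least 4 of the 8 arrays were kept (11600). Probe names came from a RefSeq gene table of assembly GRCr8, used for names only, through accessions, symbols, synonyms and gene numbers; 14319 of the 15207 probes matched, to 11716 genes, and the others kept the file's name. Probe positions are those of the files, on rn4, and no annotation of exons was used. Of several probes of a gene the brightest on average over all 8 arrays was taken, which gave 9442 genes and unnamed probes, 8889 with a gene symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with group, empirical Bayes, Benjamini-Hochberg adjustment over the 9442, threshold 0.05), so every adjusted p of a single gene comes from limma. SE is the moderated standard error of the log2 difference, PNFLX minus control.

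Where a probe was not well above background on any array of 1 group, its fold is a bound, the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Genes named in the text were chosen by a rule fixed before the data were examined: the 15 higher and 15 lower genes of largest log2 difference among those past the threshold whose groups do not overlap, then Hdac4, Htr2a, Htr2c, Htr1a, Slc6a4, Bdnf, Nr3c1, Crh and Gfap whatever their values, and up to 4 members of smallest p in each gene list described. A total of 40 lists with 1096 genes were fixed at the same time; the list of sex chromosome genes had 0 measured members, and 39 with at least 5 were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists), where missing spots were filled with the group's mean. Camera compares a list's genes with all other genes, so its direction can differ from the sign of the list's median or mean: for histone deacetylases, for microglia markers, for immediate early genes, for extracellular matrix genes and for mitochondrial biogenesis the median was below 0 and the test's direction up, like the mean, while for the lists of serotonin, neuropeptide and mTOR genes, metabotropic glutamate receptors and channels both median and mean were below 0 and the direction up, and for GABA and cytokine genes the median was above 0 and the mean below 0, with the direction up. All alternatives except those said to be chosen after seeing the data were fixed before the data were examined.

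The fits were tested on simulated data made from the means and spreads of the 9442 genes and unnamed probes in the comparison of PNFLX with control, with 200 changed. Of the genes changed 4-fold 83.3% were called, of those changed 2-fold 46.3% and of those changed 1.5-fold 7.46%, with no wrong direction, and 6 unchanged genes were called. A list of 71 genes raised 1.5-fold was the only list called. The simulated genes varied independently of each other, so this result does not cover lists whose genes are correlated. In separate simulated data with less spread, a shift of 1 log2 unit was placed alike on all probes of the outer spot rows. It was reduced by the row and column subtraction from 0.99 to -0.01 in the median. In the real data the log2 differences scattered more at the ends, with a median absolute deviation of 0.87 in the first and 1.10 in the last 5 rows, against 0.29 in rows 21 to 172. Row medians cannot remove such scatter, so a call kept after the subtraction may still come from the ends. That subtraction took, on each array, the median deviation of each spot row (running median over 5 rows, single rows at the ends) and of each block of 6 columns. Plots were drawn with matplotlib 3.10.9.

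Alternatives tried were normexp background correction of the mean brightness with an offset of 50, quantile normalization, median scaling, no scaling, the deposited table, no filter and a filter on all 8 arrays, the replicate number as a block, another variance model, array weights, each array left out in turn, every probe or the mean of all probes of a gene, other thresholds and other list tests. Added after seeing the data were the removal of 5 or 20 spot rows at each end, the row and column subtraction and the use of flagged spots.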

Results

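Whole hippocampi of rats were profiled at 2 months of age in 8 samples. As pups the animals had been given either fluoxetine, a selective serotonin reuptake inhibitor, at 10 mg/kg or a vehicle of sucrose in water at 5%, between postnatal days 2 and 21. The fluoxetine group is called PNFLX and the vehicle group control, with 4 samples in each. Labelled RNA of each sample was hybridised to 1 single-colour Agilent array with 15207 rat probes. The 75th percentile of signal ranged from 654 on control 4 to 941 on PNFLX 2, and 70.5% to 77.9% of the probes were well above background. Correlations between arrays lay between 0.948 and 0.983. The labels number the samples within each group without saying that each came from a separate animal. The p-values therefore measure the spread between these samples, and 4 arrays per group limit the precision. All 8 arrays lay on 1 slide and were scanned together, with the controls in 1 row of the slide and the PNFLX samples in the other, so slide row and group cannot be told apart.

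The comparison of PNFLX with control asks which hippocampal transcripts differ in young adults after fluoxetine in early postnatal life. The transcript with the lowest p was that of Nifk, a nucleolar protein that binds the proliferation marker Ki-67, at -1.07 ± 0.13 (SD, n = 4) in control and -5.34 ± 0.28 (SD, n = 4) in PNFLX on the log2 scale relative to the array's 75th percentile. It was 19.3-fold lower in PNFLX (log2 difference -4.27, SE 0.17, limma adjusted p = 2.84e-05), with 1 of the 4 PNFLX arrays well above background, while a second Nifk probe, well above background on 3 arrays, gave -0.11 (SE 0.30). Tm9sf2, an endosomal membrane protein, was 29.3-fold higher in PNFLX (-3.10 ± 0.47 against 1.77 ± 0.32, log2 difference 4.87, SE 0.26, adjusted p = 0.000185). Ppargc1a, the coactivator of mitochondrial biogenesis, was 7.08-fold higher (log2 difference 2.82, SE 0.34, adjusted p = 0.0161), although only 1 of the 4 controls was well above background. With normexp background correction the difference of Ppargc1a was gone (-0.022, SE 0.66). These 3 probes lay in the outermost spot rows of the array, as did most of the calls: Tm9sf2 in row 1, Ppargc1a in row 2, and Nifk in row 192 of 192. After a subtraction of each array's row and column medians, chosen after seeing the data, Tm9sf2 kept its call (3.35, SE 0.27, adjusted p = 0.00724), while Nifk (-2.22, SE 0.34, adjusted p = 0.0531) and Ppargc1a (1.40, SE 0.26, adjusted p = 0.0910) lost theirs with smaller differences.

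In all, 48 of 9442 genes and unnamed probes passed an adjusted p of 0.05 in limma, 27 higher and 21 lower in PNFLX, and in all 48 the groups did not overlap. At an unadjusted p under 0.05 there were 1204, 478 higher and 726 lower, where chance gives 472. The groups did not overlap in 11.0% of the 9442, where chance gives 2.86%. Of the 48, 20 lay in the first 5 spot rows, all higher in PNFLX, and 10 in the last 5 rows, all lower, although those 10 rows held only 398 of the 9442 (Fisher's exact test, odds ratio 40.8, 95% interval 21.8 to 78.6, two-sided p = 6.92e-30). The median log2 difference of all probes was 0.62 in the first 5 rows, -0.05 in the inner rows 21 to 172 and -0.62 in the last 5 rows. Without the first and last 5 rows, an alternative chosen after seeing the data, limma called 0 of 9085, with 1092 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0848. The 18 calls outside those rows kept their log2 differences and had lower unadjusted p, but with the small p-values of the ends gone the adjustment gave them 0.0848 to 0.111.

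**Figure D1:**
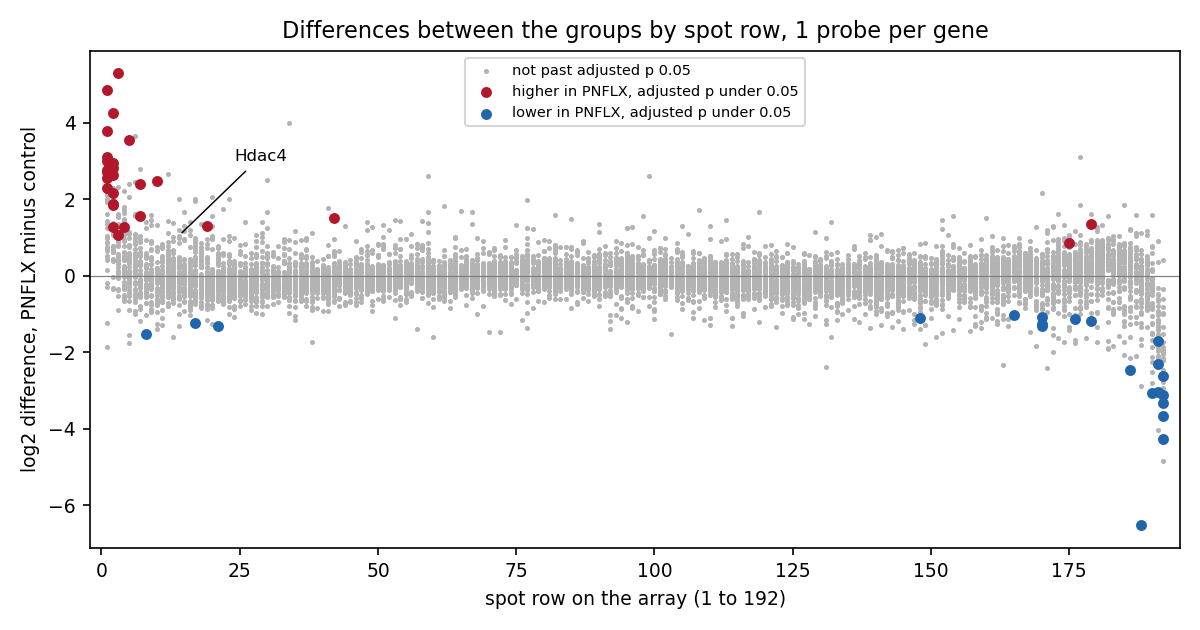
Log2 difference between PNFLX and control (vertical axis) of each of the 9442 genes and unnamed probes against the spot row of its probe on the array (horizontal axis, rows 1 to 192). Red points are higher and blue points lower in PNFLX at a limma adjusted p under 0.05, and grey points did not pass; 20 red points lie in rows 1 to 5 and 10 blue points in rows 188 to 192.

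Higher in PNFLX, beside Tm9sf2 and Ppargc1a, were Rps27a, a ubiquitin fusion protein of the small ribosomal subunit (log2 difference 5.30, SE 0.26), and Bri3, a brain membrane protein (4.27, SE 0.53). So were the zinc finger protein gene Zfp207 (2.73, SE 0.28), the DNA annealing helicase gene Smarcal1 (2.57, SE 0.18), the protease gene Tasp1 (2.65, SE 0.40) and the endothelial sialomucin gene Emcn (2.30, SE 0.33). Rps27a rested on 1 unflagged control spot, and its log2 difference was 4.01 with flagged spots kept, an alternative added after seeing the data. The controls were not well above background for 7 further genes, so their folds are bounds. Cct6a, a chaperonin subunit, was at least 7.60-fold higher, Rad50, of DNA break repair, at least 5.41-fold, Rwdd2a at least 4.43-fold, and the olfactory receptor genes Or4c1, Or52k1, Or51f23c and Or4k48 at least 4.29-fold, 4.16-fold, 4.10-fold and 3.20-fold. All of these passed an adjusted p of 0.05 in limma, and all but Or4c1 (row 10) and Or4k48 (row 7) lay in spot rows 1 to 3. Tasp1 and Emcn were well above background on 1 of the 4 controls. With normexp background correction the log2 differences of Tasp1, Rad50, Rwdd2a and all 4 olfactory receptor genes fell below 0 without passing, where the median of all genes was -0.39. Over all alternatives the log2 difference of Cct6a went down to 0.04 and that of Emcn to 0.17, with limma adjusted p of up to 0.973 and 0.879. Rwdd2a also lay just outside the threshold with flagged spots kept (2.76, limma adjusted p = 0.0510). After the row and column subtraction Rps27a (4.11), Smarcal1 (1.06) and Or4c1 still passed, Or4k48 lay just outside (adjusted p = 0.0530), and the others did not pass, with Bri3 at 2.83, Tasp1 at 1.23, Zfp207 at 1.22 and Emcn at 0.81.

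Lower in PNFLX, beside Nifk, were Prkag2, a regulatory subunit of AMP-activated kinase (log2 difference -3.66, SE 0.59), the transcription factor gene Etv1 (-3.33, SE 0.51), the proteasome gene Psmb4 (-3.03, SE 0.40) and the nuclear lamina gene Lmna (-2.32, SE 0.31). The nucleotide pyrophosphatase gene Itpa (-3.07, SE 0.27) rested on 2 unflagged PNFLX spots and did not pass with flagged spots kept (-2.42, adjusted p = 0.0511). Adgre5, an adhesion receptor of leukocytes, was at least 4.83-fold lower, the olfactory receptor gene Or6a2 at least 2.40-fold and Ucp1, the uncoupling protein of brown fat, at least 2.24-fold, since PNFLX was not well above background. Apart from Or6a2 in row 186, these lay in rows 190 to 192. Prkag2 and Etv1 were well above background on 1 of the 4 PNFLX arrays. After the row and column subtraction Or6a2 and Itpa (-2.34) still passed, while Psmb4 (-1.89), Prkag2 (-1.59), Etv1 (-1.30), Lmna (-0.92), Adgre5 (adjusted p = 0.287) and Ucp1 did not. Further from the ends were Serpinb7 (-1.31, SE 0.20, row 170), the serine protease gene Tmprss4 (-1.27, SE 0.21, row 170), Tspyl5 (-1.22, SE 0.18, row 17), the T cell coreceptor gene Cd8b (-1.19, SE 0.18, row 179) and Cox6a1, of cytochrome c oxidase (row 21). The spots of Cox6a1 were saturated on 4 control and 3 PNFLX arrays, so the size of its difference is not known and its direction is not secure. Over all alternatives its log2 difference lay between -1.43 and -0.04. Tmprss4 lay just outside the threshold with flagged spots kept, at the same difference (-1.27, limma adjusted p = 0.0510). After the row and column subtraction Serpinb7 and Cd8b still passed, while Tmprss4 (-1.27, adjusted p = 0.0910), Tspyl5 (-1.03, adjusted p = 0.0986) and Cox6a1 (adjusted p = 0.0571) did not, with differences of Tmprss4 and Tspyl5 about as large as before. A second probe of Tspyl5 gave -0.43 (SE 0.16), that of Cd8b -0.35 (SE 0.19) and that of Or6a2 1.02 (SE 0.34). None of the 3 passed when all 15207 probes were tested without the filter on dim probes. In that test, whose adjustment also counts probes not above background, the first probes of Tspyl5 and Cd8b did not pass either (adjusted p = 0.0552 and 0.0554).

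The inner rows 21 to 172 held 7 calls among 7533 genes and unnamed probes, 6 of them lower, counting the saturated Cox6a1. Beside Cox6a1, Serpinb7 and Tmprss4 they were the prostacyclin receptor gene Ptgir (-1.09, SE 0.15), the olfactory receptor genes Or10ak7e (-1.10, SE 0.16) and Or5au1 (-1.03, SE 0.15), and 1 unnamed probe that was higher (1.51, SE 0.18). Ptgir, Or10ak7e and Or5au1 fall outside the rule for named genes and were chosen after their values were seen. Leaving out controls 1 to 4 in turn left 28, 32, 15 and 17 calls in all, and leaving out PNFLX 1 to 4 left 21, 14, 60 and 20, with 17 higher and 43 lower without PNFLX 3. The row and column subtraction ended 3 of these 7 inner calls, Cox6a1, Tmprss4 and Or5au1 (adjusted p = 0.0680), though Or5au1 at -1.04 and Tmprss4 at -1.27 kept their size, and left 21 calls in all, 9 higher and 12 lower, of which 17 were among the 48.

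Hdac4, the class IIa histone deacetylase that a publication by the authors concerns in this model, was 2.07-fold higher in PNFLX on its brighter probe, at chromosome 9, 91447691 to 91447750 (rn4), from -2.76 ± 0.22 in control to -1.71 ± 0.45 in PNFLX (SD, n = 4). The groups did not overlap, and the difference did not pass over all genes (log2 difference 1.05, SE 0.24, limma adjusted p = 0.106). Its second probe, dimmer and well above background on all 8 arrays, gave a log2 difference of -0.25 (SE 0.36). Without scaling between arrays, which moved the median of all genes by 0.26, the first probe passed (1.35, adjusted p = 0.0388). Over all alternatives the adjusted p of the gene lay between 0.0388 and 0.801. This range includes the second probe, at -0.25, which was taken where the first probe's spot row was left out. The upper end of the range may therefore not be that of the first probe. Sirt1, a NAD-dependent deacetylase, was at 0.95 (SE 0.21, adjusted p = 0.103) and Hdac1 at -0.22 (SE 0.14). Of 14 histone deacetylases and sirtuins measured, 6 were higher and 8 lower and 0 passed over all genes. Adjusted over the list alone, 2 passed, Hdac4 and Sirt1, both higher, and since that list was chosen with knowledge of the study this is not independent evidence. The list as a group did not pass (limma's camera, adjusted p = 0.938), and its median was -0.11 and its mean 0.03. Without PNFLX 4, where 5 of the 14 were at their lowest, 7 were higher and 7 lower. None of 22 other chromatin and DNA methylation enzymes passed, with Kdm6b, a histone demethylase, at -0.43 (SE 0.12) and Setdb1, a histone methyltransferase, at 0.47 (SE 0.16).

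**Figure D2:**
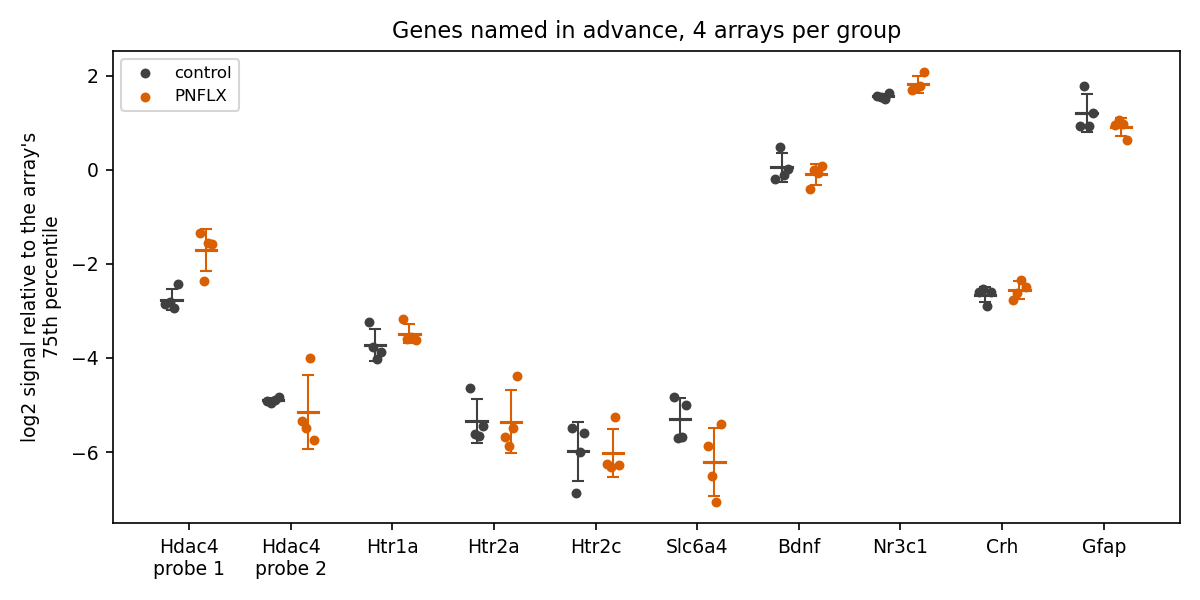
Log2 signal relative to the array's 75th percentile (vertical axis) of both Hdac4 probes and 8 other genes named in advance (horizontal axis). Each point is 1 array, with 4 control arrays in grey and 4 PNFLX arrays in orange, and bars give the mean ± SD; on probe 1 of Hdac4 the PNFLX mean of -1.71 lies above the control mean of -2.76, and on probe 2 the PNFLX arrays lie on both sides of the controls.

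Genes of the serotonin system did not pass in limma. The transporter Slc6a4, fluoxetine's target, was well above background on 3 control and 2 PNFLX arrays and at -0.91 (SE 0.38, adjusted p = 0.363), Htr1a at 0.24 (SE 0.20), Htr2a at -0.02 (SE 0.36) and Htr2c at -0.04 (SE 0.36). Among 16 measured members of this list 7 were higher and 9 lower, with Htr1b at 0.54 (SE 0.15, adjusted p = 0.177) and the degrading enzyme Maoa at 0.50 (SE 0.19). The neurotrophin Bdnf was at -0.15 (SE 0.19), the glucocorticoid receptor gene Nr3c1 at 0.25 (SE 0.13), the stress peptide gene Crh at 0.10 (SE 0.15) and the astrocyte filament gene Gfap at -0.31 (SE 0.22), and none of these 4 passed. Of 20 genes of the glucocorticoid and stress axis 7 were higher and 13 lower, with the chaperone gene Hsp90ab1 at -1.18 (SE 0.35). Of 33 neurotrophins, growth factors and receptors 14 were higher and 19 lower, with Erbb4 at -0.65 (SE 0.24). Of 15 genes of the catecholamine system 5 were higher and 10 lower, with Drd5 at -0.28 (SE 0.14).

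Among 39 gene lists 0 passed an adjusted p of 0.05, whether tested with camera at its preset correlation, camera with an estimated correlation, fry or an exact permutation test of the list means. At an unadjusted p under 0.05 the numbers were 3, 0, 1 and 1 in that order. All 5 measured erythrocyte and blood genes were higher in PNFLX, with a median log2 difference of 0.40 (camera p = 0.0036, adjusted p = 0.140, and p = 0.153 with an estimated correlation). They included Ahsp, the haemoglobin stabilising protein, at 0.64 (SE 0.21), and Alas2, of haem synthesis, at 0.40 (SE 0.17), and Ahsp passed when adjusted over the list alone. The shift lay mostly in PNFLX 1 and PNFLX 3, whose blood genes were 0.59 and 0.37 above their means in the median, while PNFLX 4 was at -0.18, within the range of the controls, and PNFLX 2 near 0. Of 16 meningeal and fibroblast markers 13 were higher, with a median of 0.35 (camera p = 0.00842, adjusted p = 0.164, and p = 0.293 with an estimated correlation), among them the collagen genes Col1a2 at 1.32 (SE 0.58) and Col3a1 at 0.79 (SE 0.32) and the proteoglycan gene Bgn at 0.57 (SE 0.23). PNFLX 1 stood apart, with 12 of the 16 at their highest, and without it the list's median was 0.10, with 9 higher and 7 lower. Without control 3 or PNFLX 3 the meningeal list passed (adjusted p = 0.0142 and 0.0258), and without PNFLX 4 the blood list did (0.0069); over all alternatives their adjusted p ranged up to 0.990.

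Of 32 genes of the presynaptic vesicle machinery 27 were lower in PNFLX and 5 higher, with a median of -0.16 (camera p = 0.0157, adjusted p = 0.204, and p = 0.217 with an estimated correlation). Vamp1, a vesicle SNARE, was at -0.53 (SE 0.15), the vesicle protein gene Syp at -0.36 (SE 0.15) and the priming factor gene Unc13a at -0.48 (SE 0.22), while Slc17a6, a vesicular glutamate transporter, was at 0.41 (SE 0.19). None of these passed singly. PNFLX 4 stood apart, with the lowest value of 17 of the 32, and without it 22 were lower and 10 higher, with a median of -0.10. Of 32 postsynaptic density genes 20 were lower and 12 higher, with the calmodulin-binding Nrgn at -0.54 (SE 0.15). Here too PNFLX 4 held the lowest value of 14, and without it 18 were lower and 14 higher. Lower too were 12 of 18 ionotropic glutamate receptors, with Gria3 at -0.86 (SE 0.36). Of 8 metabotropic glutamate receptors 4 were higher and 4 lower. Of 20 genes of GABA receptors, synthesis and transport 13 were higher and 7 lower, with Gabra4 at -0.80 (SE 0.25) and the vesicular transporter Slc32a1 at -0.52 (SE 0.17), and 7 of 15 interneuron markers were higher. Of 35 neuropeptides and their receptors 17 were higher and 18 lower, with Hcrt at 1.11 (SE 0.40) and Galr2 at -0.50 (SE 0.15).

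Of 28 genes of neurogenesis and proliferation 16 were higher and 12 lower, and 2 passed when adjusted over the list alone. These were Sox11 (1.27, SE 0.26, adjusted p over all genes 0.0908) and Dcx (0.75, SE 0.19), both markers of immature neurons, whose probes lay in rows 2 and 1. Both differences turned with the row and column subtraction, to -0.22 (SE 0.15) for Sox11 and -0.80 (SE 0.22) for Dcx. Of 27 immediate early genes 12 were higher and 15 lower, with Ptgs2 at 0.91 (SE 0.27) and Junb at -0.61 (SE 0.20). Of 40 genes of cAMP, calcium and CREB signalling 15 were higher and 25 lower, with the adenylyl cyclase Adcy5 at 0.83 (SE 0.16, adjusted p = 0.0715), which passed when adjusted over the list alone, and over all genes after the row and column subtraction (0.89, SE 0.12, adjusted p = 0.0351). Without PNFLX 4, which held the lowest value of 17 of the 40, 20 were higher and 20 lower. Of 30 mTOR and insulin signalling genes 12 were higher and 18 lower. Of 19 circadian clock genes 6 were higher and 13 lower, with 10 at their lowest on PNFLX 4, and the median moved from -0.12 to -0.06 without it.

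Of 59 genes of oxidative phosphorylation 24 were higher and 35 lower. Cox6a1 passed over all genes, and Ndufa7 (-2.24, SE 0.39, row 190, and -1.70 after the row and column subtraction), Cox6a1 and Atp5me (row 17) passed when adjusted over the list alone, all 3 lower. The spots of Atp5me were saturated on all 8 arrays and most of those of Cox6a1 were too, so the direction of these genes is not secure. Of 31 genes of mitochondrial biogenesis and antioxidant defence 14 were higher and 17 lower, with Ppargc1a the 1 that passed over all genes, and 3 passed over the list alone, the fusion factor gene Mfn1 (-1.67, SE 0.34, row 191, and -0.32 after the row and column subtraction), Ppargc1a and Sirt1. Of 71 cytosolic ribosomal protein genes 22 were higher and 49 lower (median -0.12, limma's camera, adjusted p = 0.668), and Rps27a alone passed. Of 29 proteasome genes 10 were higher and 19 lower, and Psmb4 alone passed. Of 28 genes of heat shock and the unfolded protein response 12 were higher and 16 lower. Of 25 hypoxia and glycolysis genes 7 were higher and 18 lower, with the glycolytic Gpi at -0.57 (SE 0.16), and of 24 cholesterol synthesis genes 15 were higher and 9 lower, with Cyp51 at 0.51 (SE 0.17). None of these lists passed as a group, except in alternatives. With normexp background correction the oxidative phosphorylation, ribosomal and proteasome lists passed as higher (camera, adjusted p = 6.83e-09, 8.06e-09 and 5.92e-06). Camera compares a list with all other genes, and the median log2 difference of all genes was -0.39 there. Lists that passed as higher therefore need not be higher in PNFLX. Without the outer 20 spot rows at each end the ribosomal list passed as lower (camera, adjusted p = 0.0466).

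Markers of other cell types and of neighbouring regions did not pass as groups, except in alternatives. With normexp background correction astrocyte and oligodendrocyte markers passed, both higher relative to all other genes (camera, adjusted p = 0.00652 and 0.0122). The median log2 difference of all genes was -0.39 there. Of 17 astrocyte markers 9 were higher and 8 lower, and of 20 oligodendrocyte and myelin markers 7 were higher and 13 lower. Of 16 microglia markers 7 were higher and 9 lower, with Trem2 at 0.84 (SE 0.23), and of 16 endothelial and mural cell markers 9 were higher and 7 lower. Of 10 choroid plexus markers 2 were higher and 8 lower, with a median of -0.28. The list's lowest median came from control 4, where its members lay 1.74 above their means and 7 of the 10 were at their highest, such as Sostdc1 with a signal of 2144 against 48.7 to 57.1 on the other controls. Without control 4 the median was 0.18, with 7 higher and 3 lower. Of 10 dentate gyrus markers 6 were higher, with Calb1 at 0.36 (SE 0.13), and of 16 markers of the CA fields 7 were higher, with Coch at 1.37 (SE 0.30, adjusted p = 0.105), which passed when adjusted over the list alone. Of 20 markers of thalamus, striatum, hypothalamus and cortex 8 were higher and 12 lower. Of 22 genes of the interferon response and antigen presentation 11 were higher and 11 lower, with Isg15 at 2.30 (SE 0.43, adjusted p = 0.0715, row 1, and 0.82 after the row and column subtraction), which passed over the list alone. Of 22 inflammatory cytokines and chemokines 11 were higher and 11 lower, and of 32 genes of the extracellular matrix and perineuronal nets 14 were higher and 18 lower, with Col4a1 at 1.33 (SE 0.40).

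**Figure D3:**
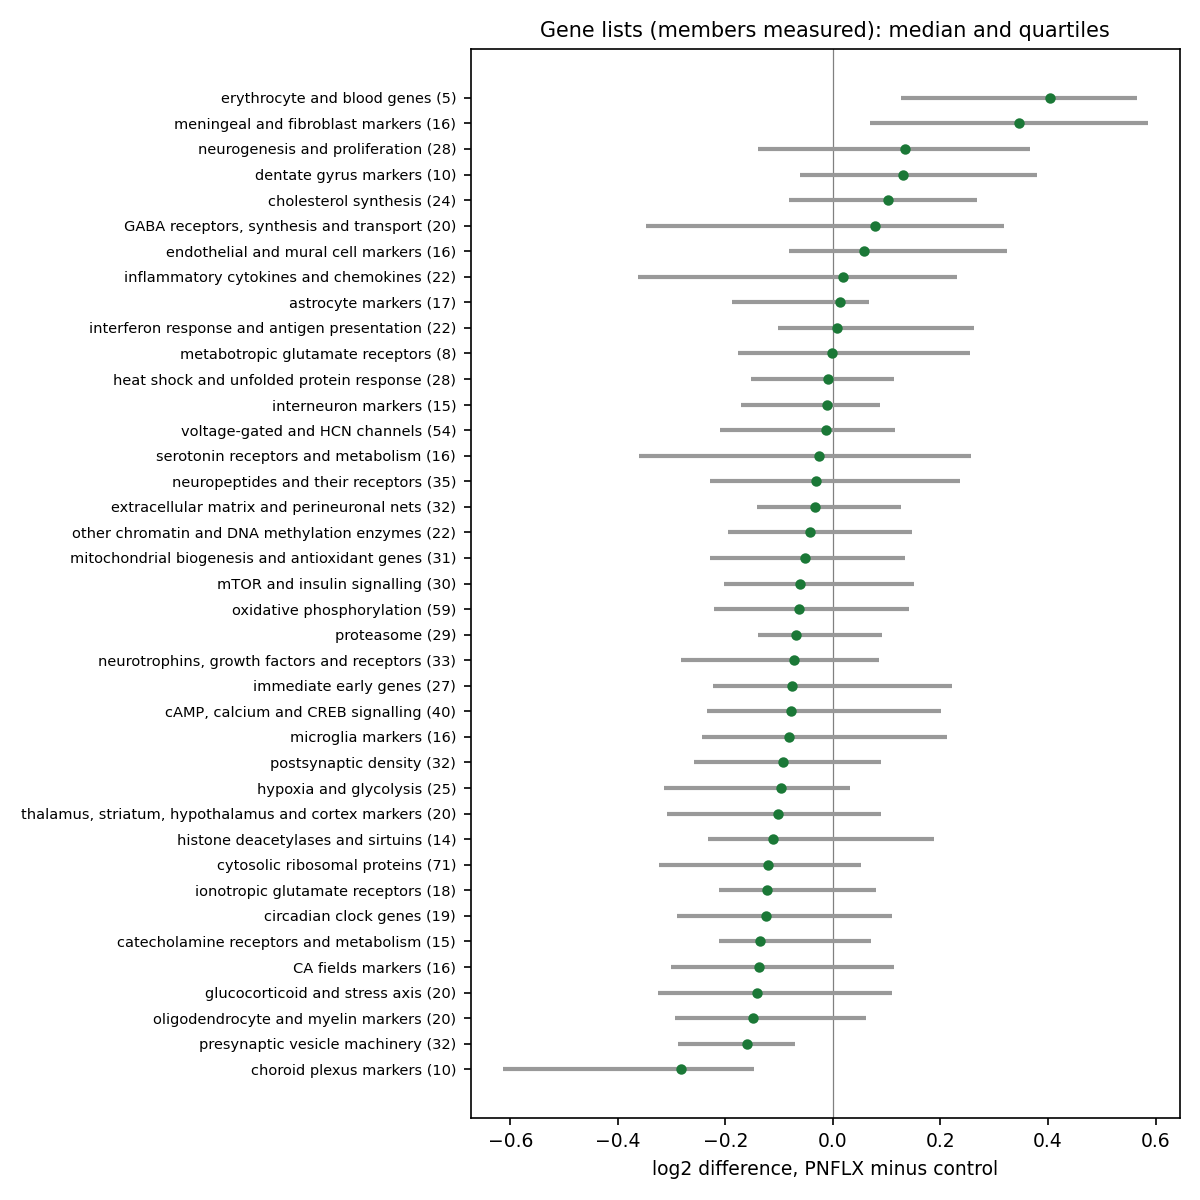
Median (green point) and quartiles (grey bar) of the log2 differences between PNFLX and control (horizontal axis) over the measured members of 39 gene lists (vertical axis, number of members in brackets). The medians run from -0.28 for choroid plexus markers to 0.40 for erythrocyte and blood genes, and 0 lists passed an adjusted p of 0.05.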

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

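The tests of control spots, raw brightness, spike-in spots, negative control spots and the Hdac4 probes were chosen after the results were seen; the test of inner probes and the count of splits for genes were set before their own results were seen. Chance puts about 1 in 20 groups of 4 past the limit used for a sample far from the others (by the gap to its neighbour as a part of the group's range), and 8 of 96 groups checked were.

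PNFLX 3 stood apart in its dimmest spots. The lowest spike-in probe, a viral sequence, had a median signal of 20.98 there against 4.02 to 6.42 on the other PNFLX arrays, a gap of 0.858 of the range. The negative control spots had a median processed signal of 6.82 against 2.14 to 2.65, a gap of 0.890. Their background-subtracted medians were negative on all 8 arrays, so these processed medians rest on the software's surrogate values for low signals and are not measured brightness. The dimmest 3802 rat probes lay 1.23 log2 units above the mean of the other arrays on PNFLX 3, and the brightest 3802 lay 0.00 above. A higher abundance of these rat transcripts would leave spike-in spots alone, and these were 3.15-fold brighter than on the next highest array, control 1. Background left on all spots is argued against by the negative control spots, whose raw brightness on PNFLX 3 lay 1.03 above the median of the other arrays (95% bootstrap interval 0.453 to 2.67) where that of the spike-in spots lay 25.6 above, and whose background-subtracted median was the lowest of the 8 arrays, -10.93. Unspecific binding to probes other than the negative controls stays open and was not tested. Htr2c, a dim probe, stood apart on PNFLX 3 too, at -5.25 against -6.33 to -6.24 on the others, a gap of 0.924.

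Control 1 correlated less with the other controls (mean r 0.969 against 0.978 to 0.979, a gap of 0.898 of the range) and with the PNFLX arrays (0.955 against 0.966 to 0.967, a gap of 0.919). Etv1 on control 4 was at -0.74 against -1.89 to -1.73 on the other controls, a gap of 0.865. Tspyl5 on PNFLX 1 was at -5.13 against -4.82 to -4.77, a gap of 0.843. Htr1a on PNFLX 1 was at -3.18 against -3.61 to -3.55, a gap of 0.865.

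The second pattern is the shift of probes at the ends of the arrays, higher in PNFLX in the first spot rows and lower in the last. If treatment had changed transcripts with probes there in general, other probes of the same genes would shift too. Over 152 genes with a kept probe in the outer 10 rows and another in rows 21 to 172, the outer probes differed by a median of 1.02. The inner ones, signed by the outer, differed by -0.018 (95% bootstrap interval -0.08 to 0.05), with 74 of 152 in the same direction. The called genes with a second kept probe, Tspyl5, Cd8b and Rab5a, all lay outside the outer 10 rows. The test therefore does not cover the genes called at the ends. Detrending by the scanner software is not the whole cause, since the raw mean brightness held the shift, a first minus last difference of 1.73 (interval 1.57 to 1.92) against 1.24 in the processed signal. Uneven hybridisation or washing at the ends, different in the 2 slide rows, remains open and may be the cause. Positive control spots differed by 2.92 (interval 1.95 to 3.83 over spots) between the ends. In the first 5 rows these were 4 bright corner spots, all higher. In the last 5 rows they were 9 bright corner spots and 1 spike-in spot, 9 of these 10 lower. Most of these spots are thus copies of the same probe, present at both ends, so the interval does not measure a spread between probes. Whether the bright corner probe carries rat sequence was not determined. The real grouping gave 48 calls and the highest of the other splits of the 8 arrays 0. So 1 of 35 splits reached 48, the smallest share this count can give, which argues against chance without excluding it. That split also follows the slide rows, while all others mix the 2 rows, so the count cannot tell treatment from slide row.

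The third pattern is Hdac4, higher on 1 of its 2 probes. A rise of all Hdac4 transcripts is argued against by the difference of 1.30 (SE 0.41, exact permutation p = 0.0286, the smallest possible) between the probes' log2 differences. A trend over spot rows is argued against by the row and column subtraction, which left 1.14 (SE 0.19, adjusted p = 0.0721) from 1.05 (SE 0.24). Wide scatter near spot row 14 could still account for it, since 3.74% of 561 neighbouring probes differed by as much or more, within their central 95% (-0.89 to 1.31). A change in a transcript that only the first probe detects stays open and was not tested.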

How the results depend on the processing

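Alternatives at the array ends, the row and column subtraction and the use of flagged spots were chosen after seeing the data. The count of 48 (27 higher, 21 lower) stayed within 1.5 times with median scaling, the deposited table, another variance model, flagged spots kept or a fold minimum, and with quantile normalization, where the split turned to 32 higher and 40 lower. It was 27 with normexp (7 higher, 20 lower, 9 shared with the 48), where the median log2 difference of all genes was -0.39, and 108 without scaling (92 higher, 16 lower). It was 26 without a filter, 25 with a filter on all 8 arrays, 78 over every kept probe and 87 with means of kept probes. At an adjusted p under 0.10 it was 144, and at an unadjusted p under 0.05 and 1.5-fold 671. Array weights, from 0.267 for PNFLX 4 to 3.86 for PNFLX 2, gave 358, of which 79 lay in the outer 10 rows. Without the outer 5 or 20 spot rows at each end it was 0; the 18 calls outside the outer 10 rows kept their log2 differences without these rows and were lost to the adjustment. It was 21 after row and column subtraction. Leaving out 1 array gave 14 to 60, the 60 without PNFLX 3 and with 17 higher and 43 lower. The causes of the other changes were not tested.

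With the replicate number as a block, which is also the slide column, 5 were called, all in the outer 10 rows. Same-numbered samples did not pair: their deviations correlated at 0.01, 0.08, 0.09 and 0.02, and 2 of the 4 numbers correlated best with their own. The block left the number of lists at 0.

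The number of lists past the threshold was 0 in most alternatives, 0 to 1 when 1 array was left out, 1 without a filter (blood genes), 3 without the outer 20 rows (blood, meningeal and, lower, ribosomal) and 7 with normexp, all higher. With normexp 6 lists turned from lower to higher, with camera p of 0.00419 for interneuron markers, 0.00748 for cAMP signalling, 1.75e-10 for oxidative phosphorylation, 4.13e-10 for ribosomal proteins, 4.56e-07 for the proteasome and 0.00156 for oligodendrocyte markers. Camera compares a list with all other genes, and the median of all genes was -0.39 there, so these lists need not be higher in PNFLX. Whether that shift is the whole cause was not tested. Normexp also turned 8 called genes from higher to lower, none past the threshold there: Rad50 at -0.21, Or52k1 at -0.40, Or51f23c at -0.30, Ppargc1a at -0.022, Rwdd2a at -0.30, Tasp1 at -0.13, Or4c1 at -0.22 and Or4k48 at -0.54. Only Or52k1 and Or4k48 lay below the median of all genes there. Of single-gene results over the alternatives 573 kept direction and side of the threshold, 223 lost the call, 1 gained it and 22 uncalled ones changed sign; of list results 843, 0, 8 and 118.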

Other observations

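The tests of this part were all chosen after the results were seen. The real grouping gave 0 lists past the threshold and the highest of the other splits of the 8 arrays 5; with a real number of 0 all 35 splits must reach it, so this count decides nothing.

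Some of the rows next to the ends moved the other way from the outermost rows. In spot rows 173 to 187 the median log2 difference was 0.20, against -1.31 in row 191 and -2.04 in row 192, and in rows 6 to 20 it was -0.10 against 1.25 in row 1. PNFLX 4 had the lowest deviation in row 192, -1.96, against -0.46 to -0.68 on the other PNFLX arrays and 0.91 to 1.32 on the controls. Of the 7 calls in rows 21 to 172, 3 (Ptgir, Serpinb7 and Tmprss4) lay in spot row 170, which held 61 genes and unnamed probes with a median difference of 0.06. Rab5a, a small GTPase of early endosomes named here after its values were seen, was higher on its brighter probe, at 0.86 (SE 0.13, limma adjusted p = 0.0316, row 175), and its second probe, at 0.66 (SE 0.25, row 169), did not pass. When all 15207 probes were tested without the filter on dim probes, the brighter probe did not pass either (adjusted p = 0.0579).

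The number at an unadjusted p under 0.05 stayed high away from the ends. Without the outer 5 spot rows at each end it was 1092, where chance gives 454, and the highest of the other 34 splits gave 845, that of control 1, 3 and 4 with PNFLX 3 against the rest.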
